A study of Homo sapiens with 12 samples.

How the data were processed

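RNA of 12 libraries of HT1080 cells, an established human fibrosarcoma line, had been sequenced after transfection of scrambled siRNA, siTRIP12, siOTUD5, or siTRIP12 and siOTUD5 together, with 3 libraries in each of the 4 groups. Per the labels, total RNA was extracted with a column kit and made into stranded poly(A) libraries. The labels do not say whether the 3 replicates of a group came from separate cultures, nor do they give the siRNA sequences or amounts. The cell line label counts up by 1 from sample to sample, starting at HT1080, while the series design names HT1080 alone, which is taken here as the line of all 12 libraries. Submitters' processing notes name HISAT2, StringTie and the genome build GRCh38, without versions, roles or order.

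The deposited table gives, per gene and library, read counts as whole numbers, made by the authors. Beside them stand FPKM values, which the authors had scaled to transcript length and library size. The FPKM were used only to derive an effective transcript length per gene from the ratio of count to FPKM. Whether the authors counted reads or fragments was not stated. Of 71969 values of 1 to 20 reads, 51.1% were even. All 12 per-sample columns were mapped to a group by their names. Of the 46427 gene IDs in the table, 44698 were in the reference gene table used for names, coordinates and gene types, whose release may differ from that used by the authors.

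Library totals ranged from 37912312 to 43881471 reads. At this depth a gene without a read in a group is given a bound from a floor of 3 counts over the group, which covers counting error only.

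Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr on the 4 groups, which left 16283 genes and removed 30144. TMM factors scaled the libraries, and normalised read counts were computed with them as CPM, the count scaled to the adjusted library total. A quasi-likelihood model with robust estimation and a mean per group was fitted to all 12 libraries (8 residual degrees of freedom, biological coefficient of variation 0.0822). Quasi-likelihood F-tests compared siTRIP12, siOTUD5 and siTRIP12+siOTUD5 with scrambled, and siTRIP12+siOTUD5 with each knockdown alone. The interaction was the difference between siTRIP12+siOTUD5 and siOTUD5 minus the difference between siTRIP12 and scrambled. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called, and adjusted p of single genes are from this edgeR test. Levels of TRIP12 and OTUD5 were also compared by an exact two-sided permutation test, whose smallest p with 3 against 3 libraries is 0.1.

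Before the data were examined, 29 gene lists with 693 genes were fixed (14 genes stood in more than 1 list, and 15 symbols were matched through aliases). They covered inflammation, p53, cell cycle, stress responses, metabolism, chromatin, the ubiquitin system, adhesion and matrix, and markers of epithelial cells, leukocytes, and endothelial and muscle cells. Each list was tested in the 6 comparisons with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over all lists and comparisons. Camera with an estimated correlation and fry were run beside it. Members of a list were counted by their adjusted p over all genes and adjusted over the list alone.

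The rule for naming genes was also fixed before the data were examined. Each comparison with scrambled names TRIP12, OTUD5, and the 8 largest rises and 8 largest falls in fitted log2 fold change among called protein-coding genes. These genes had a mean of at least 100 reads in the higher group and no overlap between the libraries of the groups. Comparisons without scrambled and the interaction name 5 rises and 5 falls. For a list, up to 4 members with the smallest p are named. Results of some single genes that met the rule are not reported here. Log2 fold changes are given with their standard error (SE), and CPM as mean ± SD.

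Alternatives fixed beforehand were DESeq2 size factors, upper-quartile factors, no filter, a minimum mean of 50 reads, a replicate block, a test against a fold of 1.5 (glmTreat), limma-voom, DESeq2 1.42.0, fits on only the groups compared, and leaving out each library in turn. Halved counts, all libraries except scrambled replicate 3, list tests under other scalings, filters and libraries, and leaving out genes with a 3′ UTR site of the sequences below were added after the data had been seen. Other splits of the libraries were refitted to see how many genes they call. For the interaction, residuals of log2 CPM from an additive fit of the 2 siRNAs were also regrouped and tested with limma, a test added after the data had been seen.

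Effects of a knockdown in the 2 backgrounds of the other siRNA were compared across genes by Pearson's r, Spearman's rho and a total-least-squares slope, without TRIP12 and OTUD5. For the correlation of the siTRIP12 and siOTUD5 changes, which share the scrambled libraries, 20 sets of counts were simulated in which all groups had equal means. After the data had been seen, annotated 3′ UTRs (GENCODE release 29) of 10070 genes with a mean of at least 4 CPM and a 3′ UTR of at least 30 bases were scanned in Python 3.11.15. For each sequence of 7 or 6 bases found in at least 50 genes, log2 changes of genes with and without it were compared by a z that accounts for length and GC content of the 3′ UTR.

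The steps were tested on simulated data. With 50 genes changed 2-fold among 16267, the comparison of siTRIP12 with scrambled called 45 in the right direction and the interaction 42. With a change of 1.5-fold the numbers were 32 and 26, and 14 and 5 unchanged genes were called. A list shifted by 0.3 on the log2 scale had an estimated median of 0.30 and was called, and of the other 28 lists 0 were called. Genes were drawn independently of each other, so this does not test the preset inter-gene correlation. A slope of 0.5 was estimated at 0.499. In 20 of 20 draws the scan ranked first a sequence whose genes had been lowered by 0.1.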

Results

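Gene expression was measured by RNA sequencing in HT1080 fibrosarcoma cells in which TRIP12, a HECT-domain ubiquitin ligase, or OTUD5, an OTU-family deubiquitylase, or both, had been knocked down by siRNA. The series title places the work in the study of a combinatorial ubiquitin code and its removal. Scrambled siRNA, siTRIP12, siOTUD5 and siTRIP12+siOTUD5 were represented by 3 libraries each. Totals ranged from 37912312 reads in siTRIP12 replicate 3 to 43881471 in siTRIP12 replicate 1, and 16283 of 46427 genes had enough reads to be tested. The first principal component held 23.1% of the variance and separated the libraries with siTRIP12 (13.8 to 32.7) from those without it (-34.0 to -11.1). The second held 16.3% and separated the libraries with siOTUD5 (-26.5 to -14.1) from those without it (15.7 to 26.8). Scrambled replicate 3 lay apart from its group on the third component (-35.8, with 10.9 as the lower value of its other 2 libraries).

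TRIP12 (NCBI gene 9320, GRCh38 chromosome 2, 229763837 to 229923186) fell from 322 ± 39.8 CPM in scrambled to 41.8 ± 3.92 CPM in siTRIP12 (n = 3 each), which is 13.0% of the scrambled level. In siTRIP12+siOTUD5 it was at 53.2 ± 2.70 CPM, or 16.5%. In siOTUD5 it was at 315 ± 1.76 CPM, with a log2 fold change of -0.03 ± 0.08 (adjusted p = 0.834). OTUD5 (gene 55593, chromosome X, 48922024 to 48958381) fell from 59.8 ± 1.13 CPM to 11.1 ± 0.749 CPM in siOTUD5 and to 10.9 ± 1.34 CPM in siTRIP12+siOTUD5, which are 18.6% and 18.2% of the scrambled level. It rose to 123% of that level in siTRIP12 (log2 0.30 ± 0.07, adjusted p = 0.0035). All 3 libraries lay beyond all 3 scrambled libraries in each of these 5 changes, where the exact permutation p was 0.1, the smallest that 3 against 3 libraries can give.

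**Figure D1:**
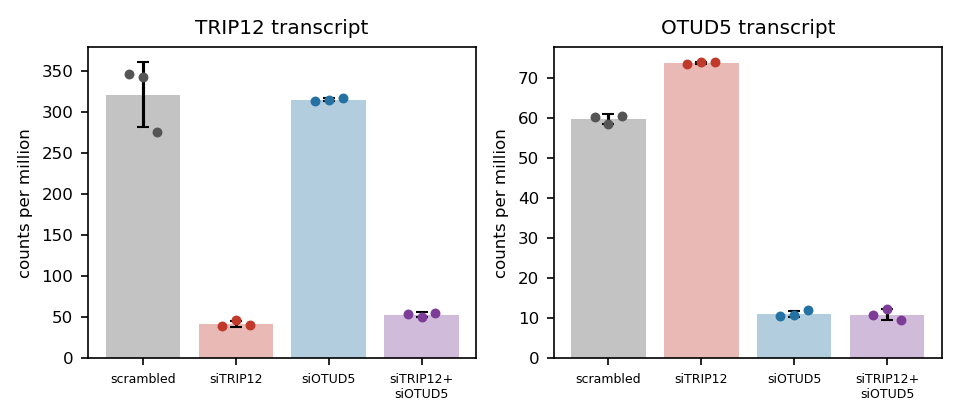
Normalised read counts (CPM) of TRIP12 and OTUD5 in each library (points), with the mean of the 3 libraries of a group (bars) and the SD (whiskers). TRIP12 was at 13.0% and 16.5% of the scrambled level in the 2 groups given siTRIP12, and OTUD5 at 18.6% and 18.2% in the 2 groups given siOTUD5.

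Knockdown of TRIP12 alone was compared with scrambled siRNA. The largest rise was that of ESM1, a secreted proteoglycan (gene 11082, chromosome 5, 54977867 to 54985593), from 0.363 ± 0.0317 to 14.7 ± 2.12 CPM (log2 5.32 ± 0.19, adjusted p = 2.3e-12). The hair keratin-associated gene KRTAP2-3 rose from 2.28 ± 0.50 to 44.6 ± 5.23 CPM. KRTAP2-1, KRTAP2-2 and KRTAP2-4 rose by log2 4.21, 4.16 and 4.58, but these paralogs are similar in sequence and neighbours on chromosome 17, so their reads may not be separable. MYCT1 (log2 3.07 ± 0.12), the stromelysin gene MMP3 (3.06 ± 0.13) and KYNU, an enzyme of tryptophan breakdown (2.53 ± 0.27), followed. MMP9, which encodes a gelatinase, fell from 29.5 ± 1.80 to 3.07 ± 0.120 CPM (log2 -3.26 ± 0.10, adjusted p = 4.8e-13). The acute-phase genes SAA1 and SAA2 (log2 -2.25 ± 0.11 and -2.14 ± 0.14, near-identical paralogs), the cytokine gene IL32 (-1.81 ± 0.10), the TNF receptor adaptor TRAF1 (-1.81 ± 0.11), UCN2 (-1.84 ± 0.13), FPR1 (-2.06 ± 0.22) and CA9 (-2.11 ± 0.53) fell as well. The CA9 call was lost when only the groups compared were fitted (adjusted p = 0.0776).

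Among the lists, 22 genes of the NF-kB and TNF response were measured, of which 12 fell, 4 rose and 6 were not called (13 and 4 called when adjusted over the list alone). The median log2 change was -0.32 (camera adjusted p = 0.0015, adjusted p = 0.25 with an estimated correlation). TRAF1, the apoptosis inhibitor BIRC3 (log2 -1.56 ± 0.14) and the cytokine gene IL11 (-0.83 ± 0.07) fell, and the collagenase MMP1 rose (1.54 ± 0.14). Of 25 genes of G1/S and DNA replication, 19 fell and 1 rose (20 and 1 adjusted over the list alone), with a median of -0.33 (adjusted p = 6.3e-07, adjusted p = 0.28 with an estimated correlation). They included the helicase subunits MCM4 (-0.57 ± 0.05) and MCM7 (-0.42 ± 0.05) and the nuclease FEN1 (-0.41 ± 0.05). Of 28 MYC targets and genes of ribosome biogenesis, 16 fell (17 over the list alone), among them NOP58 (-0.48 ± 0.07). That list had a median of -0.20 (adjusted p = 7.1e-05, adjusted p = 0.28 with an estimated correlation).

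Replication-dependent histone genes rose in siTRIP12. Of 15 measured, 11 were higher and 0 lower, also adjusted over the list alone, with a median of 0.85 (adjusted p = 3.4e-06, adjusted p = 0.14 with an estimated correlation). H2AC6 reached 22.3 ± 1.97 CPM (log2 1.02 ± 0.09) and H2BC12 from 204 to 282 CPM (0.47 ± 0.05). Most transcripts of such genes lack a poly(A) tail, and 14 structured RNAs of at least 5 CPM that also lack it, of which 9 were rRNA copies, had a median of 0.85 in the same comparison, with 2 called. In the extracellular matrix list, 11 of 27 genes fell and 5 rose, with the same counts over the list alone and a median of -0.18 (adjusted p = 0.0014, adjusted p = 0.41 with an estimated correlation). SPARC, a collagen-binding glycoprotein, fell from 986 to 604 CPM, and the collagen genes COL7A1 (-1.50 ± 0.12) and COL5A1 (-0.94 ± 0.09) fell. Of 19 hypoxia and glycolysis genes 12 fell and 3 rose, the same over the list alone (median -0.23, adjusted p = 0.0068, adjusted p = 0.61 with an estimated correlation), among them the pyruvate dehydrogenase kinase PDK1 (-0.68 ± 0.08) and lactate dehydrogenase LDHA (-0.45 ± 0.05). Of 23 p53 targets, 8 rose and 4 fell (9 and 6 over the list alone; median 0.08, adjusted p = 0.022, adjusted p = 0.18 with an estimated correlation). CDKN1A, the gene of the cell-cycle inhibitor p21, rose by 0.71 ± 0.06 and GDF15 by 1.59 ± 0.12.

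In all, 5194 genes differed between siTRIP12 and scrambled, 2367 higher and 2827 lower, and 514 of them by more than 2-fold. With upper-quartile scaling the split was 2964 higher and 2232 lower, so the balance of directions depended on the scaling. Against a fold of 1.5 (glmTreat) 276 genes were called.

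Knockdown of OTUD5 alone was compared with scrambled siRNA. MYCT1 rose from 5.44 ± 0.671 to 26.5 ± 3.10 CPM (log2 2.28 ± 0.12, adjusted p = 1.4e-09). SYNE1, which encodes a nuclear envelope protein and lies next to MYCT1 on chromosome 6 (152121687 to 152637362, against 152697897 to 152747181), rose from 40.4 ± 6.27 to 116 ± 8.58 CPM. The genes of the cytokine IL1B (log2 1.51 ± 0.13), the glutathione-degrading enzyme CHAC1 (1.71 ± 0.34), NTNG2 (1.59 ± 0.27), IGFN1 (1.39 ± 0.18) and CD22 (1.37 ± 0.08) rose. The 3′ UTR of CD22 holds GACGTA, the 6-base sequence most raised against scrambled, as do those of 415 of the 10070 genes scanned. TMEM225B had 0 reads in scrambled and 694 in siOTUD5, at least 230-fold higher with a floor of 3 counts over the group. It had no read in 5 of the 12 libraries and 118 to 273 in the other 7, and its call (adjusted p = 0.035) was lost with any of the 3 scrambled or 3 siOTUD5 libraries left out (highest adjusted p = 0.0867), with a replicate block (0.0721) and without a filter (0.0546). The largest fall was that of TOMM22, a subunit of the mitochondrial import receptor, from 109 ± 11.9 to 23.4 ± 0.960 CPM (log2 -2.22 ± 0.07, adjusted p = 1.0e-12). The nuclear lamina protease ZMPSTE24 (-1.35 ± 0.08), the proline synthesis enzyme ALDH18A1 (-1.25 ± 0.06), the mitochondrial topoisomerase TOP1MT (-1.42 ± 0.08), NACA (-1.10 ± 0.07), RGS4 (-1.46 ± 0.12), LRRC15 (-1.39 ± 0.25) and PMVK (-1.10 ± 0.12) also fell. The 3′ UTR of TOMM22 holds 2 copies of GTTTGAA, the 7-base sequence most lowered in this comparison, and those of RGS4, ZMPSTE24 and NACA hold 1 each. So does that of ANKRD1, which rose. GTTTGAA was in 1634 of the 10070 genes scanned and was picked in this same comparison, so these sites are no separate evidence.

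p53 targets were higher in siOTUD5, with 16 of 23 risen and 1 fallen (17 and 1 over the list alone) and a median of 0.27 (adjusted p = 1.2e-10). This list was also called with an estimated correlation (adjusted p = 0.0094). SESN2, a stress-induced regulator of growth signalling, rose by 1.15 ± 0.08, CDKN1A by 0.75 ± 0.06, and MDM2, which encodes the ubiquitin ligase of p53, by 0.42 ± 0.06. Of 24 genes of the ATF4 and amino acid response, 18 rose and 1 fell, with the same counts over the list alone (median 0.57, adjusted p = 4.9e-10, adjusted p = 0.31 with an estimated correlation). The lipoprotein receptor VLDLR rose by 1.11 ± 0.09 and the cystine transporter SLC7A11 by 1.18 ± 0.14. In cholesterol synthesis 15 of 21 genes fell and 0 rose (17 and 1 over the list alone), with a median of -0.26 (adjusted p = 1.7e-07, adjusted p = 0.14 with an estimated correlation), including INSIG1 (-0.71 ± 0.06) and HMGCS1 (-0.51 ± 0.06). Of 16 heat shock proteins 13 fell and 0 rose, as over the list alone (median -0.23, adjusted p = 1.2e-06, adjusted p = 0.33 with an estimated correlation).

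Among 22 NF-kB and TNF response genes 8 rose and 2 fell in siOTUD5, also over the list alone (median 0.23, adjusted p = 7.6e-04, adjusted p = 0.23 with an estimated correlation). IL1A rose by 1.00 ± 0.12 and IL11 by 0.58 ± 0.07. YAP and TAZ targets rose in 11 of 23 cases and fell in 2 (12 and 2 over the list alone; median 0.21, adjusted p = 2.4e-05, adjusted p = 0.32 with an estimated correlation), with ANKRD1 at 0.72 ± 0.06. Immediate early and AP-1 genes rose in 12 of 23 cases and fell in 2 (13 and 2 over the list alone; median 0.18, adjusted p = 2.3e-05, adjusted p = 0.098 with an estimated correlation), with the survival factor MCL1 at 0.62 ± 0.05. Of 25 genes of G1/S and DNA replication 14 fell and 0 rose (15 and 0 over the list alone; median -0.21, adjusted p = 3.8e-05, adjusted p = 0.32 with an estimated correlation). Of 25 genes of G2/M and mitosis 12 fell and 1 rose (13 and 2 over the list alone; median -0.22, adjusted p = 3.0e-04, adjusted p = 0.31 with an estimated correlation). Of 29 genes of the DNA damage response and homologous recombination 11 fell and 0 rose (13 and 0 over the list alone; median -0.16, adjusted p = 7.6e-04, adjusted p = 0.14 with an estimated correlation), with FANCD2 at -0.85 ± 0.06.

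In all, 3781 genes differed between siOTUD5 and scrambled, 1849 higher and 1932 lower, and 212 by more than 2-fold. With upper-quartile scaling 1986 were higher and 1785 lower, and with DESeq2 size factors 1896 and 1856. Against a fold of 1.5, 78 were called. Levels ran lower in longer transcripts most in scrambled replicate 3 (rho of -0.31 with transcript length across genes), which enters all 3 comparisons with scrambled, and in siTRIP12 replicate 3 (-0.22), and higher most in siOTUD5 replicate 2 (0.20) and siTRIP12+siOTUD5 replicate 3 (0.18).

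Both knockdowns together were compared with scrambled siRNA. MYCT1 reached 77.5 ± 8.44 CPM (log2 3.83 ± 0.12) and SYNE1 172 ± 2.90 CPM (2.09 ± 0.09). KRTAP2-3 was at 19.5 ± 2.95 CPM (3.09 ± 0.16), and IL1B (1.61 ± 0.13), CHAC1 (1.86 ± 0.34) and the zinc finger gene ZNF404 (1.88 ± 0.10) rose. TMEM225B, with 614 reads, was at least 209-fold higher, and its call was lost with any of the 6 libraries compared left out (highest adjusted p = 0.074) and with a replicate block (0.0651). MMP9 fell by log2 -2.11 ± 0.09, TOMM22 by -1.71 ± 0.07, the calcium-binding protein CALB2 by -1.94 ± 0.13, DAZAP2 by -1.53 ± 0.07, PMVK by -1.51 ± 0.13 and the kinase MAP2K6, with 3 copies of GTTTGAA and 1 of GTTCAGA in its 3′ UTR, by -1.49 ± 0.13. Of the 10070 genes scanned, 1634 held GTTTGAA and 1126 held GTTCAGA. CA9 (-2.05 ± 0.53) was no longer called without siTRIP12+siOTUD5 replicate 1 or 2 (highest adjusted p = 0.0632). ASDURF (-1.90 ± 0.41) shares its locus with ASNSD1, so its reads may belong to either.

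**Figure D2:**
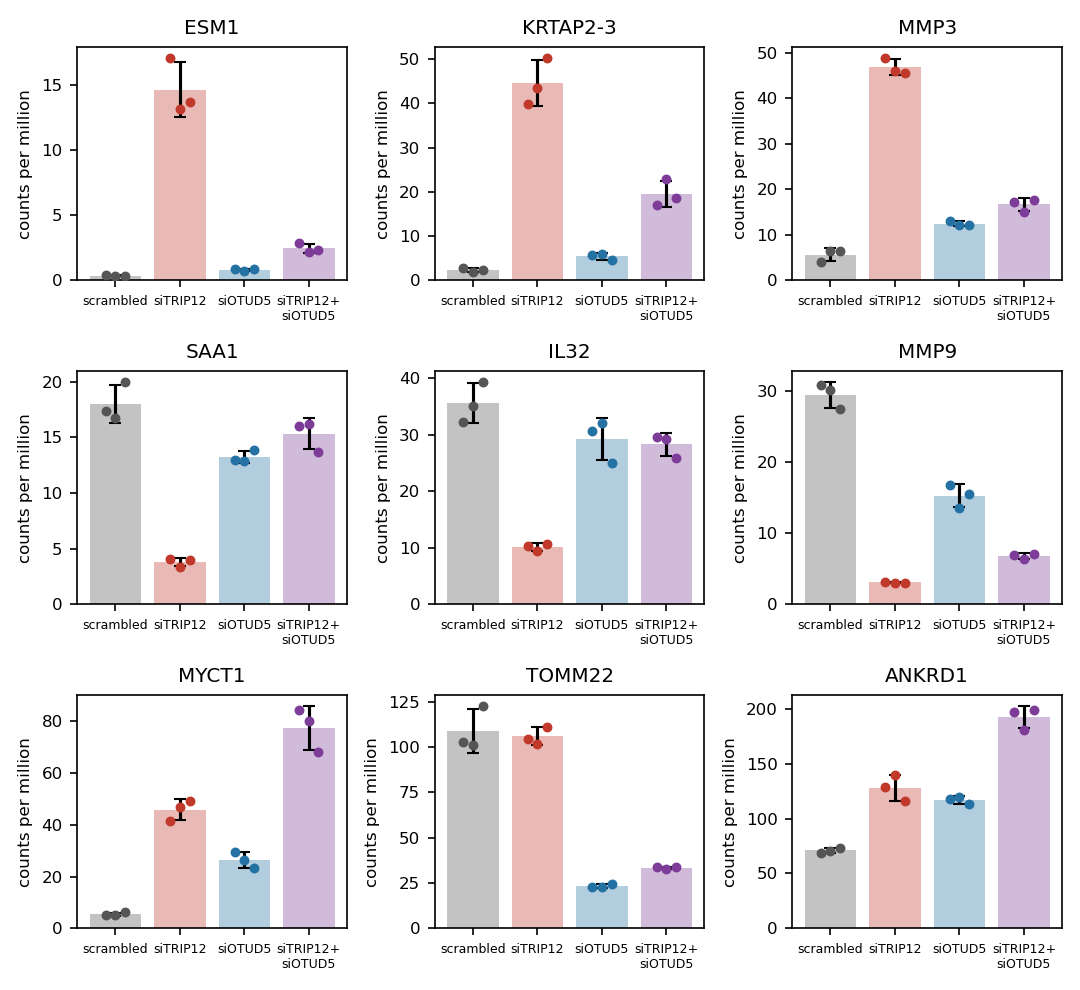
Normalised read counts (CPM) of 9 named genes in each library (points), with group means of 3 libraries (bars) and SD (whiskers); each vertical axis starts at 0. ESM1 stood at 14.7 CPM in siTRIP12 and 2.45 CPM in siTRIP12+siOTUD5, and MYCT1 was highest in siTRIP12+siOTUD5, at 77.5 CPM.

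With both knockdowns, 16 of 24 ATF4 and amino acid response genes rose and 0 fell (17 and 0 over the list alone; median 0.61, adjusted p = 1.2e-10, adjusted p = 0.31 with an estimated correlation), among them DDIT3 (1.22 ± 0.14) and ATF3 (0.64 ± 0.08). Of 21 cholesterol synthesis genes 16 fell and 0 rose (19 and 0 over the list alone; median -0.29, adjusted p = 1.0e-08, adjusted p = 0.14 with an estimated correlation), including INSIG1 (-0.79 ± 0.06). Of 23 p53 targets 12 rose and 0 fell (12 and 2 over the list alone), with a median of 0.20 (adjusted p = 2.6e-05). The call held with an estimated correlation (adjusted p = 0.036). YAP and TAZ targets rose in 11 of 23 cases and fell in 1, as over the list alone (median 0.15, adjusted p = 1.2e-05, adjusted p = 0.31 with an estimated correlation). ANKRD1 rose from 71.1 to 193 CPM and the Hippo kinase LATS2 from 50.8 to 80.5 CPM. NF-kB and TNF response genes rose in 10 of 22 cases and fell in 3, as over the list alone (median 0.27, adjusted p = 0.0050, adjusted p = 0.29 with an estimated correlation), with CXCL8 at 1.12 ± 0.15. In G1/S and DNA replication 14 of 25 genes fell and 2 rose, as over the list alone (median -0.19, adjusted p = 0.0031, adjusted p = 0.47 with an estimated correlation). In all, 5024 genes differed, 2394 higher and 2630 lower (2722 and 2214 with upper-quartile scaling), 370 by more than 2-fold and 159 against a fold of 1.5.

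siTRIP12+siOTUD5 was compared with siTRIP12 to show what adding siOTUD5 changed where TRIP12 was already low. TRIP12 was at 53.2 CPM with both siRNAs and 41.8 CPM in siTRIP12, and GTTCAGA, the 7-base 3′ UTR sequence most lowered in siTRIP12, was the most raised of 16087 here (z of 6.29), so changes back toward the scrambled level are not separated from weaker siTRIP12 action. SAA1 rose from 3.80 ± 0.385 to 15.3 ± 1.38 CPM (log2 2.01 ± 0.11, adjusted p = 3.1e-09), SAA2 by 2.00 ± 0.14, BIRC3 from 2.64 to 7.44 CPM, IL32 by 1.48 ± 0.10 and the complement gene C3 by 1.28 ± 0.12. ESM1 fell from 14.7 to 2.45 CPM (-2.58 ± 0.15), MMP3 from 46.8 to 16.7 CPM (-1.49 ± 0.12), KYNU by -1.55 ± 0.25 and KRTAP2-4 by -1.49 ± 0.25. TOMM22 fell by -1.67 ± 0.07. Of 22 NF-kB and TNF response genes 16 rose and 1 fell (19 and 1 over the list alone), with a median of 0.50 (adjusted p = 8.8e-19). This call held with an estimated correlation (adjusted p = 0.011). TRAF1 rose by 1.28 ± 0.11, IL11 by 1.13 ± 0.07 and NFKBIA, which encodes an inhibitor of NF-kB, by 0.63 ± 0.07.

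Replication-dependent histones were lower than in siTRIP12 in 8 of 15 cases and higher in 0 (9 and 0 over the list alone; median -0.71, adjusted p = 2.4e-09, adjusted p = 0.066 with an estimated correlation), with H2AC6 at -1.23 ± 0.09. The 14 structured RNAs without a poly(A) tail had a median of -0.39 here. Cholesterol synthesis genes fell in 11 of 21 cases and rose in 1 (15 and 1 over the list alone; median -0.22, adjusted p = 8.9e-08, adjusted p = 0.14 with an estimated correlation). YAP and TAZ targets rose in 10 of 23 cases and fell in 1 (12 and 1 over the list alone; median 0.23, adjusted p = 1.7e-07, adjusted p = 0.28 with an estimated correlation), with the kinase NUAK2 at 1.07 ± 0.09. Of 26 apoptosis and cell death regulators 8 rose and 0 fell, as over the list alone (median 0.13, adjusted p = 2.5e-04, adjusted p = 0.14 with an estimated correlation). BIRC3 and MCL1, which restrain cell death, and CYCS (0.53 ± 0.07), which promotes it, were among those that rose. In all, 2557 genes differed, 1429 higher and 1128 lower (1254 and 1271 with upper-quartile scaling, 1130 and 1132 without a filter), 128 by more than 2-fold and 34 against a fold of 1.5. Without siTRIP12+siOTUD5 replicate 1 the count was 1495.

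**Figure D3:**
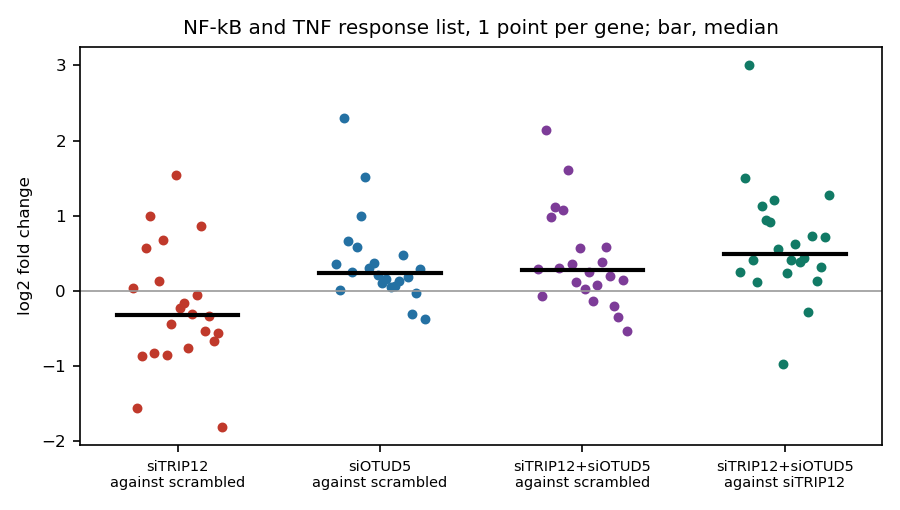
Log2 fold changes of the 22 measured genes of the NF-kB and TNF response list (points) in 4 comparisons, with the median of each (bars). Medians were -0.32 in siTRIP12, 0.23 in siOTUD5 and 0.27 in siTRIP12+siOTUD5 against scrambled, and 0.50 in siTRIP12+siOTUD5 against siTRIP12.

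siTRIP12+siOTUD5 was compared with siOTUD5 to show what TRIP12 knockdown changed where OTUD5 was already low. KRTAP2-3 rose from 5.43 ± 0.736 to 19.5 ± 2.95 CPM (log2 1.84 ± 0.14), KRTAP2-4 by 1.62 ± 0.29, MYCT1 by 1.55 ± 0.10, ZNF404 by 1.55 ± 0.10 and ZNF582 by 1.21 ± 0.18. CALB2 (-1.41 ± 0.13), UCN2 (-1.28 ± 0.13), KCNAB3 (-1.28 ± 0.25), FPR1 (-1.26 ± 0.20) and PLXNA4 (-1.23 ± 0.16) fell, and the 3′ UTR of PLXNA4 holds 2 copies of GTTCAGA. Immediate early and AP-1 genes fell in 10 of 23 cases and rose in 1 (10 and 3 over the list alone; median -0.14, adjusted p = 1.8e-04, adjusted p = 0.14 with an estimated correlation), with the signalling inhibitor SPRY2 at -0.48 ± 0.06. Matrix genes fell in 9 of 27 cases and rose in 1 (10 and 3 over the list alone; median -0.09, adjusted p = 9.2e-04, adjusted p = 0.40 with an estimated correlation), with MMP2 at -0.51 ± 0.06. Of 19 hypoxia and glycolysis genes 4 fell and 0 rose (8 and 0 over the list alone; median -0.16, adjusted p = 2.0e-04, adjusted p = 0.46 with an estimated correlation). In all, 1370 genes differed, 545 higher and 825 lower (678 and 700 with upper-quartile scaling), 75 by more than 2-fold and 14 against a fold of 1.5. The count was 784, 712 and 740 without siOTUD5 replicates 1, 2 and 3 and 692 and 809 without siTRIP12+siOTUD5 replicates 1 and 3, but 2936 with only the groups compared and 2474 with scrambled replicate 3 left out of the fit, an alternative added after the data had been seen.

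Across 16281 genes, the changes with siTRIP12 in the presence and absence of siOTUD5 had a Pearson r of 0.296 and a Spearman rho of 0.419. Genes are not independent replicates, so no p is given. Of 5580 genes called in either comparison, 79.8% changed in the same direction. Of the 981 called in both, 943 had the same direction and 38 the opposite. The changes with siOTUD5 in the presence and absence of siTRIP12 had an r of 0.151 and a rho of 0.306. Of 5206 genes called in either, 73.3% had the same direction, and of 1129 called in both, 1025 had the same direction and 104 the opposite. Slopes of 0.425 and 0.440 ranged from 0.269 to 0.789 and from 0.199 to 1.35 when single libraries were left out, and give no ratio of effect sizes.

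**Figure D4:**
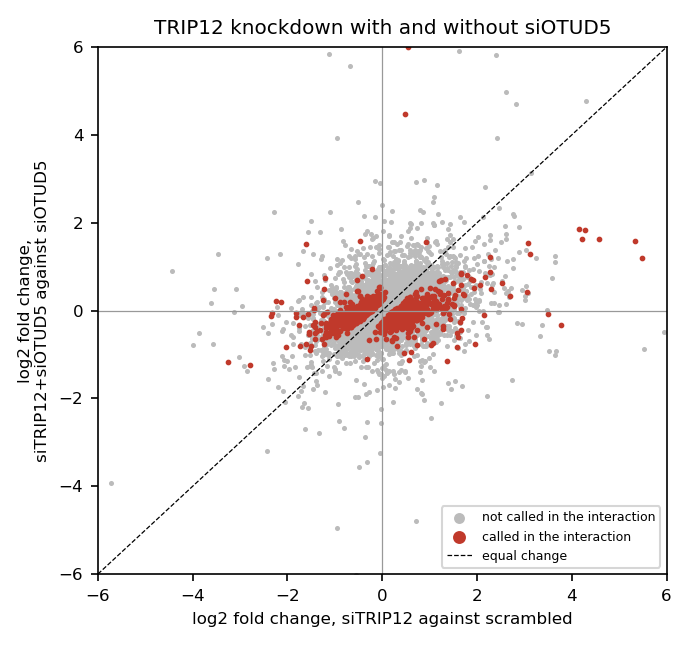
Log2 fold change of siTRIP12+siOTUD5 against siOTUD5 (vertical) and of siTRIP12 against scrambled (horizontal) for 16248 genes (points); 33 genes lie beyond 6 on an axis and are not shown. Red points are genes called in the interaction, and the dashed line marks equal change.

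siTRIP12 and siOTUD5 calls overlapped in 1937 genes, 825 higher in both, 865 lower in both and 247 in opposite directions. Lists drawn independently would share 269 higher and 335 lower genes and 602 in opposite directions. Both comparisons use the same scrambled libraries, and those numbers take no account of it. Across genes the r of the 2 changes was 0.501, against a mean of 0.497 in 20 simulations with groups of equal means and shared scrambled libraries (highest 0.575). The covariance, at 0.149, lay above the highest of the simulations (0.0645, with a mean of 0.0547). With a minimum mean of 50 reads the covariance was 0.0636. No simulation was made with that filter, so an excess is not shown for genes with more reads. The simulations held no effect of the scrambled siRNA itself, so the excess over all genes tested does not separate such an effect from changes common to both knockdowns.

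The interaction asked whether the siTRIP12 change differed with siOTUD5. It was called for 1329 genes, 751 higher and 578 lower, and 553 and 638 with upper-quartile scaling and 561 and 565 without a filter. ESM1 had an interaction of log2 -3.73 ± 0.27 (adjusted p = 1.9e-07), MMP3 of -2.64 ± 0.17, KRTAP2-4 of -2.96 ± 0.45, KRTAP2-1 of -2.58 ± 0.33 and KRTAP2-3 of -2.44 ± 0.21, as the rises with siTRIP12 were smaller beside siOTUD5. SAA1 (2.46 ± 0.15), SAA2 (2.33 ± 0.19), MMP9 (2.10 ± 0.14), IL32 (1.77 ± 0.14) and TRAF1 (1.65 ± 0.15) had positive values, as they fell less with siTRIP12, or not at all, beside siOTUD5. Of 25 genes of G1/S and DNA replication, 13 had a positive interaction and 0 a negative one (20 and 0 over the list alone; median 0.32, adjusted p = 4.0e-11, adjusted p = 0.15 with an estimated correlation). Of 22 NF-kB and TNF response genes, 7 were positive and 1 negative (8 and 2 over the list alone; median 0.31, adjusted p = 7.1e-05, adjusted p = 0.14 with an estimated correlation). Of 23 p53 targets 4 were negative and 0 positive (9 and 0 over the list alone; median -0.16, adjusted p = 1.6e-05), a call that held with an estimated correlation (adjusted p = 0.036). Scrambled enters the interaction with a positive sign. GACGTA was the most lowered of 4096 sequences in it (z of -15.9), and GTTCAGA the most raised of 16087 (z of 5.9). Of 328 interaction calls among genes higher in all 3 knockdown groups than in scrambled, 327 were negative, and all 287 among genes lower in all 3 were positive. These genes were picked by their difference from the same scrambled libraries, which by itself favours these signs. The counts therefore decide nothing about a cause. The count of 1329 was 846 without siTRIP12 replicate 3, 844, 782 and 734 without siOTUD5 replicates 1, 2 and 3, and 765 and 768 without siTRIP12+siOTUD5 replicates 1 and 3, and 34 against a fold of 1.5.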

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

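The tests of carry-over read in siOTUD5, of the S-phase share, of weaker siTRIP12 action, of the dependence of list changes on OTUD5, of regrouped residuals, and of seed-directed lowering, base composition and scrambled replicate 3 for the 3′ UTR sequences were chosen after the results were seen. The change with siTRIP12 differed between the 2 OTUD5 backgrounds, by the interaction term, for 1329 genes. The same term asks whether the change with siOTUD5 differed with siTRIP12. It does not separate dependence of 1 knockdown on the other from effects of the scrambled siRNA. Nor does it separate it from weaker action of either siRNA beside the other. In the interaction GACGTA was the most lowered 6-base sequence (z of -15.9) and GTTCAGA the most raised 7-base sequence (z of 5.9). GTTTGAA had rank 32 among the raised (z of 3.61), where sequences of the same bases reached 4.39. OTUD5 itself was at 18.6% of the scrambled level in siOTUD5 and 18.2% in siTRIP12+siOTUD5. The real grouping called more than any of 99 drawn regroupings of the 12 libraries, whose highest count was 639. Such regroupings mix libraries given different siRNAs, so they ask about any difference between the groups. With the main effects of both siRNAs removed from log2 CPM, the real grouping called 1301 genes by limma, and the highest of 99 regroupings of the residuals called 4. The residuals still held the interaction, which regrouping spreads within the groups, so these low counts do not measure noise alone. Only the real one, 1 of 100, reached its count in either test, which argues against a chance assignment of these libraries to the groups. The labels do not say whether replicates came from separate cultures. A difference between cultures that goes with a group is therefore not excluded. The 5 pairwise comparisons allow only 10 splits each, too few for a share under 0.05. In each of them 1 split, the real one, called as many genes, and the highest other split called 1 gene in the comparisons of siTRIP12 (5194) and siOTUD5 (3781) with scrambled and of siTRIP12+siOTUD5 with siOTUD5 (1370), and 0 in those of siTRIP12+siOTUD5 with scrambled (5024) and with siTRIP12 (2557).

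By the same term 11 lists differed between backgrounds. Median interactions were positive for G1/S and DNA replication (0.32), NF-kB and TNF response (0.31), type I interferon response (0.22), G2/M and mitosis (0.18), DNA damage response and homologous recombination (0.18), heat shock proteins (0.17) and MYC targets and ribosome biogenesis (0.16). They were negative for replication-dependent histones (-0.60), ATF4 and amino acid response (-0.18), p53 targets (-0.16) and immediate early and AP-1 genes (-0.12). With an estimated correlation only p53 targets were called (adjusted p = 0.036), and the 10 others had adjusted p from 0.14 to 0.68. By fry the ATF4 and heat shock lists were not called (adjusted p = 0.29 and 0.10), nor was the interferon list with a minimum mean of 50 reads (adjusted p = 0.072). Leaving out 1 library ended the call of the interferon list in 10 cases, the AP-1 list in 8, the heat shock list in 3 and the ATF4 list in 2, with adjusted p up to 0.13, 0.093, 0.092 and 0.16.

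Negative log2 interactions of single genes were those of ESM1 (-3.73), KRTAP2-4 (-2.96), MMP3 (-2.64), KRTAP2-1 (-2.58), KRTAP2-3 (-2.44), KRTAP2-2 (-2.31), KYNU (-1.90), MYCT1 (-1.52), NTNG2 (-1.52), CD22 (-1.32), MMP1 (-1.18), GDF15 (-1.12), SYNE1 (-1.09) and IGFN1 (-1.02). Smaller negative values were those of SLC7A11 (-0.97), H2BC5 (-0.90), H2BC4 (-0.79), CDKN1A (-0.79), DUSP4 (-0.75), SPRY4 (-0.69), BBC3 (-0.63), VLDLR (-0.51), H2AC6 (-0.51), SESN2 (-0.50), SPRY2 (-0.42), CCNA2 (-0.38) and ATF3 (-0.36). Positive values were those of SAA1 (2.46), SAA2 (2.33), MMP9 (2.10), IL32 (1.77), TRAF1 (1.65), BIRC3 (1.49), C3 (1.01), ZNF404 (0.63), TOP1MT (0.57), TOMM22 (0.55), DAZAP2 (0.53), ZMPSTE24 (0.48), MCM4 (0.47), RRM2 (0.46), HMMR (0.44), SOD2 (0.43) and PARP9 (0.42). MCM3 (0.38), CENPA (0.39), IER3 (0.38), ALDH18A1 (0.38), NACA (0.38), NOP58 (0.37), BRCA1 (0.35), DKC1 (0.32), CHEK1 (0.32), AURKA (0.31), NOLC1 (0.30), HSPH1 (0.30) and NOP56 (0.28) followed. Leaving out 1 library ended the call for CHEK1 in 11 cases, for ATF3, BBC3, BRCA1 and PARP9 in 10, for HSPH1 in 8, for CENPA, NOP58 and VLDLR in 5, for DKC1 and H2AC6 in 4, for AURKA in 2, and for NOP56 and SLC7A11 in 1. Further genes had the values 0.83 (CYCS), 0.69 (COL7A1), 0.58 (NFKBIA), 0.55 (IL11), 0.49 (NUAK2), 0.46 (PDK1), 0.44 (ND6), 0.39 (MCM7), 0.35 (CDC6), 0.34 (SPARC), 0.32 (LDHA and UNG) and 0.30 (FEN1 and AURKB), or -0.74 (LCP1), -0.48 (CD68), -0.42 (NEU1), -0.41 (ULK1), -0.28 (CRIM1) and -0.25 (RRS1), and these were not rerun under the alternatives. The interactions of KRTAP2-2, KYNU, MYCT1, NTNG2, CD22, SYNE1, IGFN1 and C3 were not rerun either. Nor were those of ZNF404, TOP1MT, TOMM22, DAZAP2, ZMPSTE24, ALDH18A1 and NACA, so whether these calls hold under the alternatives is not known. TRIP12 itself had 0.38, a call lost with any of 9 libraries left out. With all libraries, other scalings, filters or tools, halved counts or a replicate block ended the calls of TRIP12 and BBC3 in 5 settings each (adjusted p of 0.056 to 0.072 and 0.050 to 0.091), of HSPH1 in 4 (0.053 to 0.070), of CHEK1 and PARP9 in 3 (0.059 to 0.074 and 0.052 to 0.054), of ATF3 in 2 (0.055 and 0.058) and of BRCA1 in 1 (0.051).

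The NF-kB and TNF response list was lower in siTRIP12 than in scrambled (adjusted p = 0.0015, but 0.25 with an estimated correlation) and higher in siTRIP12+siOTUD5 than in siTRIP12 (adjusted p = 0.011 with an estimated correlation). Sites for the 3 sequences below in the members' own 3′ UTRs are argued against as the whole cause, since the 15 of 22 members without a site had a median of 0.41 in siTRIP12+siOTUD5 against siTRIP12, and 14 of them were above 0. Members with a site had a median of 0.72, so sites as a part of the cause stay open. A trend with transcript length is argued against as well, since the list median was 0.52 after that trend was removed. That the TRIP12 knockdown effect on this list differs with OTUD5 is a hypothesis that stays open, as the interaction was called with the preset correlation but had an adjusted p of 0.14 (0.1432) with an estimated one. Weaker action of siTRIP12 beside siOTUD5, with no other change, would leave the list at or under the scrambled level. With both siRNAs its median was 0.27 (0.2731) above scrambled, with 10 of 22 members called higher and 3 lower. This bound cannot decide, because siOTUD5 alone raised the list (median 0.23, 8 called higher and 2 lower). In siTRIP12+siOTUD5 against siOTUD5 the list median was 0.01, with 1 called higher and 2 lower. TRIP12 was at 16.5% of the scrambled level in siTRIP12+siOTUD5 and at 13.0% in siTRIP12. GTTCAGA was the most raised sequence in siTRIP12+siOTUD5 against siTRIP12 (z of 6.29). Weaker siTRIP12 action therefore stays open. So do changes that follow from other transcripts lowered by the siRNAs, which were not tested.

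3 short sequences went with changes of the transcripts that hold them in the 3′ UTR. GTTCAGA (1126 genes) was the most lowered of 16087 sequences in siTRIP12 against scrambled (z of -8.79) and, with no library shared, in siTRIP12+siOTUD5 against siOTUD5 (z of -7.12); GTTTGAA (1634 genes) was the most lowered in siOTUD5 against scrambled (-9.17) and in siTRIP12+siOTUD5 against siTRIP12 (-6.69). GACGTA (415 genes) was the most raised of 4096 sequences in all 3 comparisons with scrambled (12.8, 14.4 and 12.4), and scrambled replicate 3 alone is argued against, since siTRIP12 against scrambled replicate 1 gave 13.4 (13.39) and siOTUD5 against replicate 2 gave 14.8, each the most raised. In siTRIP12+siOTUD5 against scrambled GTTTGAA was the most lowered (-6.67), but GTTCAGA had rank 5 (-4.53). In the interaction GACGTA was the most lowered (-15.9), GTTCAGA the most raised (5.9), and GTTTGAA had rank 32 among the raised (3.61). In the single knockdowns against scrambled, sequences made of the same bases reached at most -6.10 for the siOTUD5 sequence, -3.94 for the siTRIP12 sequence and 5.34 for GACGTA in siOTUD5. The 3 sequences were picked there as the most lowered or raised, so none could pass them. Base composition is argued against for GTTCAGA and GTTTGAA by the comparisons that share no library with those. Sequences of the same bases reached at most -3.87 in siTRIP12+siOTUD5 against siOTUD5 and -2.81 in siTRIP12+siOTUD5 against siTRIP12. For GACGTA every such comparison shares scrambled libraries. Same-base sequences came nearer to GTTCAGA in siTRIP12+siOTUD5 against scrambled (-3.82) and passed GTTTGAA in the interaction (4.39). These values are consistent with seed-directed lowering by each siRNA, the scrambled one included, a hypothesis that the siRNA sequences, which the labels do not give, could settle.

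Replication-dependent histones were higher in siTRIP12 than in scrambled (adjusted p = 3.4e-06, but 0.14 with an estimated correlation). Carry-over of RNA without poly(A) could not be read from all 184 small structured RNA genes (median 0.0022), which lay near the floor at a median of 0.598 CPM in scrambled, so that the bound set beforehand decides nothing. The 14 such RNAs of at least 5 CPM had a median change of 0.85 in siTRIP12, with 2 called, and of 0.96 in siOTUD5, with 5 called, while the histone median in siOTUD5 was 0.01 (0.01058). Their mean log2 CPM was highest in siTRIP12 replicate 1 (8.66, with 7.82 and 7.85 in the other 2) and siOTUD5 replicate 2 (8.70, with 7.91 and 7.88), and these libraries also had the highest histone means of their groups (2.35 and 1.65), so carry-over may add to the rise. In the other libraries of these groups, where the structured RNAs were no higher in siTRIP12 than in siOTUD5, histone means were 1.90 and 2.12 in siTRIP12 and 1.33 and 1.26 in siOTUD5, against 1.33 to 1.40 in scrambled, which argues against carry-over as the whole cause. A larger share of cells in S phase is argued against, as far as G1/S genes track it, by the fall of that list (median -0.33). An effect of TRIP12 knockdown that does not depend on OTUD5 stays open, as the list had a median of 0.23 in siTRIP12+siOTUD5 against siOTUD5 (adjusted p = 0.14) and its interaction was called with the preset correlation (adjusted p = 2.6e-05) and by fry (adjusted p = 0.0013), but had an adjusted p of 0.14 with an estimated correlation. The 14 structured RNAs had a median interaction of -1.58, in the direction of the histones (-0.60), and a median of -0.39 in siTRIP12+siOTUD5 against siTRIP12, where histones had -0.71, so that carry-over is not excluded as a part of these changes.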

How the results depend on the processing

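Halved counts, leaving scrambled replicate 3 out of the fit, leaving out genes with a sequence site, and list tests under other scalings, filters and libraries were alternatives chosen after the data had been seen. None of 310 named gene results and 62 list results reversed under any alternative run, and 97 and 4 of them were called under all, glmTreat and the estimated correlation included. Against a fold of 1.5 (glmTreat), a stricter question, the counts were 276 for siTRIP12, 78 for siOTUD5 and 159 for siTRIP12+siOTUD5 against scrambled, 14 against siOTUD5, 34 against siTRIP12 and 34 in the interaction. For siTRIP12+siOTUD5 against siOTUD5 the count was 2936 with only the groups compared and 2474 without scrambled replicate 3 in the fit. Against siTRIP12 it was 3825 without scrambled replicate 3 in the fit. Scrambled libraries have no weight in these 2 comparisons and enter them only through the shared filter, scaling and estimate of spread. The main counts of 1370 and 2557 thus depend on libraries outside the comparison, and which of these routes acted was not tested. With 1 library of the groups compared left out, and so fewer samples, counts ranged from 692 to 932 against siOTUD5, from 1495 to 2057 against siTRIP12, and from 734 to 1794 in the interaction; with any of the 12 left out, the slopes across genes ranged from 0.269 to 0.789 for TRIP12 and from 0.199 to 1.35 for OTUD5. Of 62 list calls 4 were called with an estimated correlation. With a replicate block the counts were 5036, 3634, 4863, 1220, 2396 and 1140, in the order above. Same-numbered libraries of different groups did not pair (mean r of -0.0039 over 18 pairs, against 0.0019 between other numbers). Without genes holding a sequence site 3982, 2857, 3804, 1066, 1910 and 927 genes were called, and the other alternatives moved no count by more than 1.5 times. Depth, at 37912312 to 43881471 reads per library, left a group without a read at up to 3 counts.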

Other observations

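Other gene groups moved in some comparisons. MYC targets and ribosome biogenesis genes fell in 12 of 28 cases and rose in 1 in siOTUD5 against scrambled (15 and 2 adjusted over the list alone; median -0.14, adjusted p = 0.022, adjusted p = 0.48 with an estimated correlation), a call lost without siOTUD5 replicate 3 (adjusted p = 0.12). They fell in 13 and rose in 1 with both knockdowns (16 and 3 over the list alone; median -0.17, adjusted p = 0.0021, adjusted p = 0.33 with an estimated correlation). Proteasome subunits, which degrade ubiquitylated proteins, fell in 8 of 31 cases in siOTUD5 (9 over the list alone; median -0.11, adjusted p = 0.0052, adjusted p = 0.68 with an estimated correlation) and in 9 with both knockdowns (9 over the list alone; median -0.09, adjusted p = 0.023, adjusted p = 0.71 with an estimated correlation), and 0 rose in either. Both calls were lost without scrambled replicate 3 (adjusted p = 0.17 and 0.35) and by fry (0.090 and 0.097), and that with both knockdowns with a minimum mean of 50 reads (0.056) and with upper-quartile scaling (0.051). Heat shock proteins fell in 9 of 16 cases with both knockdowns (10 over the list alone; median -0.23, adjusted p = 4.2e-04, adjusted p = 0.49 with an estimated correlation), among them the co-chaperone BAG3 (-0.35 ± 0.05). Hypoxia and glycolysis genes fell in 9 of 19 cases and rose in 3, as over the list alone (median -0.19, adjusted p = 0.021, adjusted p = 0.64 with an estimated correlation), and this was not called without siTRIP12+siOTUD5 replicate 2 (adjusted p = 0.059). Autophagy and lysosome genes rose in 7 of 23 cases and fell in 3 in siTRIP12 (8 and 3 over the list alone; median 0.05, adjusted p = 0.036, adjusted p = 0.31 with an estimated correlation), with GABARAPL1 at 0.74 ± 0.07, and were not called without scrambled replicate 1 (adjusted p = 0.064). ATF4 and amino acid response genes rose in 9 of 24 cases and fell in 1 there (11 and 1 over the list alone; median 0.23, adjusted p = 0.0027, adjusted p = 0.63 with an estimated correlation).

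In siTRIP12+siOTUD5 against siTRIP12, 5 of 24 ATF4 genes rose and 1 fell (7 and 1 over the list alone; median 0.32, adjusted p = 6.3e-05, adjusted p = 0.51 with an estimated correlation), and 5 of 19 NRF2 targets fell and 0 rose (8 and 0 over the list alone; median -0.13, adjusted p = 0.0072, adjusted p = 0.32 with an estimated correlation), among them NQO1 (-0.33 ± 0.07). G1/S and DNA replication genes rose in 7 of 25 cases and fell in 1 (11 and 1 over the list alone; median 0.14, adjusted p = 0.0052, adjusted p = 0.50 with an estimated correlation). Matrix genes rose in 9 of 27 cases and fell in 1 (9 and 2 over the list alone; median 0.10, adjusted p = 0.022, adjusted p = 0.58 with an estimated correlation), a call lost without siTRIP12+siOTUD5 replicate 3 (adjusted p = 0.051). Immediate early and AP-1 genes rose in 10 of 23 cases and fell in 1 (10 and 4 over the list alone; median 0.08, adjusted p = 0.034, adjusted p = 0.31 with an estimated correlation), a call lost without siTRIP12 replicate 1 or siTRIP12+siOTUD5 replicate 2 (highest adjusted p = 0.23), with a minimum mean of 50 reads (0.072) and without a filter (0.057). Both lists had lower medians in siTRIP12+siOTUD5 than in siOTUD5. Heat shock proteins fell in 3 of 16 cases and rose in 0, as over the list alone (median -0.10, adjusted p = 0.012, adjusted p = 0.63 with an estimated correlation), and were not called without siTRIP12 replicate 1 (adjusted p = 0.066) or by fry (0.066). p53 targets rose in 5 of 23 cases and fell in 1, as over the list alone (median 0.09, adjusted p = 0.045, adjusted p = 0.25 with an estimated correlation), and were not called without siTRIP12 replicate 1 or 2 or siTRIP12+siOTUD5 replicate 2 (highest adjusted p = 0.11), nor with halved counts, a minimum mean of 50 reads, a replicate block or upper-quartile scaling (adjusted p of 0.058 to 0.094). Cytosolic ribosomal proteins had a median of 0.12 with 1 of 34 called (adjusted p = 0.0031, adjusted p = 0.70 with an estimated correlation, 0.18 by fry). DNA damage response and homologous recombination genes had a median of 0.06 in siTRIP12+siOTUD5 against siOTUD5 with 3 of 29 higher and 0 lower (4 and 0 over the list alone; adjusted p = 0.013, adjusted p = 0.25 with an estimated correlation). G2/M and mitosis genes had a median of 0.11 in siTRIP12+siOTUD5 against siOTUD5 with 4 of 25 higher (6 over the list alone; adjusted p = 0.0077, adjusted p = 0.41 with an estimated correlation), and mitochondrially encoded transcripts 0.18 with 1 of 13 higher (adjusted p = 0.036, adjusted p = 0.68 with an estimated correlation, 0.30 by fry). The mitochondrial call was lost without siOTUD5 replicate 2 or 3 or siTRIP12+siOTUD5 replicate 1 or 2 (highest adjusted p = 0.16), and without scrambled replicate 3 in the fit (0.078). Leukocyte markers, of which 6 of 18 were measured, had a median of -0.35 against siTRIP12 with 3 lower (adjusted p = 0.048, adjusted p = 0.28 with an estimated correlation), and leaving out any of 5 libraries (highest adjusted p = 0.11), upper-quartile scaling (0.053) or no filter (0.38) ended this call. The lists of chromatin remodelling and heterochromatin, epithelial markers, endothelial and muscle markers, TGF-beta targets, the unfolded protein response, Wnt and beta-catenin targets, and ubiquitin ligases and deubiquitylases of specific chains were not called by camera in any of the 6 comparisons. Of these 42 tests 3 had an unadjusted camera p under 0.05, and fry, which does not compare a list with other genes, called 15. These were 5 of Wnt and beta-catenin targets (lowest adjusted p = 3.4e-04, with both knockdowns against scrambled), 4 of the unfolded protein response (4.9e-04, in siTRIP12), 3 of endothelial and muscle markers (0.0044, with both knockdowns against scrambled), 2 of epithelial markers (0.0027, in siTRIP12) and 1 of TGF-beta targets (0.0076, in siTRIP12).

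The mean difference between genes with and without GTTCAGA was -0.0834 in siTRIP12 against scrambled and -0.0389 in siTRIP12+siOTUD5 against siOTUD5, a ratio of 0.466 ± 0.085 (SE). For GTTTGAA the values were -0.0612 and -0.0386, a ratio of 0.631 ± 0.117. GTTCAGA occurs 1 time in the TRIP12 transcript, where 29.4% of 7-base sequences occur, and GTTTGAA 1 time in the OTUD5 transcript, where 14.2% do. GTTTGAA also occurs 2 times in the TRIP12 transcript, more often than GTTCAGA.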
